A study of Danio rerio with 9 samples.

How the data were processed

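RNA was sequenced from 9 samples of zebrafish embryos, 3 of wild type, 3 of a kdm4aa knockout and 3 of a kdm4ab knockout. Per the labels' protocols, total RNA was extracted with Trizol, messenger RNA was selected on poly-T beads, and fragmented RNA was copied with random hexamers and sequenced on an Illumina platform. The stage of the embryos was not given in the sources used here. The deposited table holds 1 whole-number count per Ensembl gene and library, not normalized, for 32520 genes. The submitters' processing notes name the genome builds GRCz11 and danRer11, and the aligner, the counting tool, the annotation release and the strand setting are not given in the sources used here. Reads shared by near-identical copies of a gene, overlapping genes and antisense genes can therefore be split in ways that the counts do not show. Each column name matched the description of 1 sample, and groups and replicate numbers came from the titles.

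Library totals ran from 27894551 to 46156237 counts. Of the 32520 genes, 5076 had no count in any library. Symbols were looked up by Ensembl identifier in a table of names that covered 29201 of the identifiers. The table gives many zebrafish genes in capitals, and 1719 symbols are carried by more than 1 identifier, so for those the paralog meant by the symbol is uncertain and the identifier is printed with it where it is first named. A table of genes on the assembly GRCz12tu, which differs from the submitters' builds, placed genes on chromosomes by their symbols. Its positions set the windows around the targeted genes, and none of its coordinates are printed. Neighbours were tested genes that follow each other in the deposited counts, within a run of genes placed on the same chromosome.

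Counts were filtered with edgeR's filterByExpr, scaled by trimmed mean of M values (TMM) and tested with edgeR 4.0.16 in R 4.3.3. The quasi-likelihood F-test was used on a model with 1 mean per group and all 9 libraries, which share 1 estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Every adjusted p of a gene given without another name is from this test, and all tests are two-sided unless stated otherwise. Levels are in CPM, the rate of counts in a TMM-scaled library, computed here from the deposited counts, as mean ± SD over 3 libraries. Fold changes are edgeR's log2 values. Standard errors (SE) were computed here as the absolute log2 value divided by the square root of the F statistic. They are approximate, above all for genes with few counts in a group. The comparisons were the kdm4aa knockout against wild type, the kdm4ab knockout against wild type, and the kdm4aa knockout against the kdm4ab knockout. The last of these tests whether the knockouts differ. Nothing in the labels says that the replicates came from separate clutches, so the p-values measure only the spread between these samples, which may be technical. The chi-square between any 2 replicates of a group was at least 10.2 per gene, so no pair agreed within sampling noise.

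Bounds are given for the genes with the largest fitted changes of a comparison. Where all libraries of a group were at 0, their fold is a lower bound against 3 counts per library. Where a group had 1 to 3 counts in all, the ratio of the group rates is given with an exact 95% interval (Clopper-Pearson). For other genes with such low groups, such as list members, the fitted value is printed. These bounds and intervals cover counting error only, because reads without molecular identifiers are not independent molecules. The fitted log2 value of a gene with so few counts depends on the prior count and is no bound.

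The comparisons, tests, alternatives, gene lists and the rule for naming genes were fixed before the data were examined. The text names kdm4aa, kdm4ab and cyp26a1. For each comparison it draws on the 10 called genes with the highest and the 10 with the lowest fitted log2 fold change, among genes with a mean of at least 5 CPM in 1 of the groups, no overlap between the groups and an informative symbol. From gene lists it names up to 4 members with the smallest p. Some genes that this rule takes, though counted, are not reported here. Genes outside this rule are marked as chosen after their values were seen.

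The 29 lists held 952 names, of which 835 matched a gene of the table. They cover retinoic acid metabolism and signalling, hox genes, the DNA damage response with stress-induced arrest and death genes, apoptosis machinery, the KDM4 family, other histone lysine demethylases, H3K9 and H3K36 methyltransferases, pluripotency and blastula genes, maternal oocyte transcripts and primordial germ cells. Tissue lists cover somite and skeletal muscle, cardiac muscle, erythroid cells and globins, myeloid and innate immune cells, endothelial cells, neural progenitors and neurons, neural crest and pigment cells, lens crystallins, photoreceptors, notochord and cartilage, hatching gland, epidermis with ionocytes and periderm, yolk syncytial layer with liver and lipoproteins, and exocrine and endocrine pancreas with intestine. The remaining lists are the cell cycle, heat shock and the unfolded protein response, the interferon response, mitochondrial genome transcripts and cytosolic ribosomal proteins. Each list with at least 5 tested members was tested with limma's camera at a preset inter-gene correlation of 0.01 and with a correlation estimated per list, both adjusted over the 28 lists tested. Camera compares a list with all other genes. The fry test asked whether a list's genes move one way. Members called were also counted after adjustment over the list alone.

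The overlap of both knockouts was set beside 20 simulations of unchanged groups against the same controls. Called genes within 10 Mb of each targeted gene, by position on GRCz12tu, were compared with other placed genes by Fisher's exact test. Alternatives were DESeq2 1.42.0, limma-voom 3.58.1, other scaling factors, other filters, a fold threshold, only the compared groups in the fit, a replicate block and leaving out each library. The kdm4ab knockout replicate 2 library stood apart from the other 8. That the counts of genes and of list members called are also given without it was decided after the data were seen, and robust dispersion estimates and voom with sample quality weights were added then. Which lists are described with examples was also chosen then.

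The code was tested on counts simulated from the wild-type means and these libraries' depths. In each run 200 genes were changed by known folds, 50 per fold size. Each gene had the spread estimated in the fit, the same in all libraries. With 9 libraries that spread was widened by the library that stood apart, so the shares called need not be those of the real comparisons. In the simulated comparison of the kdm4aa knockout with wild type, run on 17983 genes, 0% of changes of 1.5-fold, 2% of 2-fold, 36% of 4-fold and 70% of 8-fold were called. Without the library that stood apart, on 18664 genes, the shares were 54%, 84%, 100% and 100%. For the kdm4ab knockout they were 0%, 8%, 36% and 64% on 18038 genes. Without that library, on 18650 genes, they were 32%, 74%, 98% and 100%. Of simulated calls, 3.98% to 10% were of unchanged genes. A list of 20 changed genes was called in every run, and 0 of 20 unchanged lists were. Genes were drawn uncorrelated, so the preset correlation was not checked.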

Results

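Poly-A RNA was measured in whole zebrafish embryos of 3 genotypes with 3 libraries each: wild type, a knockout of kdm4aa and a knockout of kdm4ab. Both genes encode histone lysine demethylases of the KDM4 family, which remove methyl groups from lysines 9 and 36 of histone H3. The study asked which genes lie downstream of kdm4aa in embryos that developed slowly and had more dying cells, and it singled out cyp26a1, which encodes an enzyme that degrades retinoic acid. Library totals were 40555109, 38509567 and 45298764 counts in wild type, 36830737, 34325902 and 44230837 counts in the kdm4aa knockout, and 46156237, 27894551 and 39039825 counts in the kdm4ab knockout.

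The kdm4ab knockout replicate 2 library stood apart from the other 8. It held 14247 genes with a count, against 22025 to 23019 in the others, and 21793 to 22566 when these were thinned to its total. Its correlation with the other libraries of its group was 0.922 to 0.929 across genes, on log2 CPM, where all other pairs within a group had 0.997. Genes are not independent replicates, so these correlations carry no p. Of genes at 1 to 5 CPM in the other kdm4ab knockout libraries, 40.7% had no count in it, and of those at 50 to 500 CPM 0.334% had none. With this library the biological coefficient of variation was 47.5%, and without it 13.1%. As all groups share 1 estimate of the spread, this library also widens the spread used to compare the kdm4aa knockout with wild type.

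**Figure D1:**
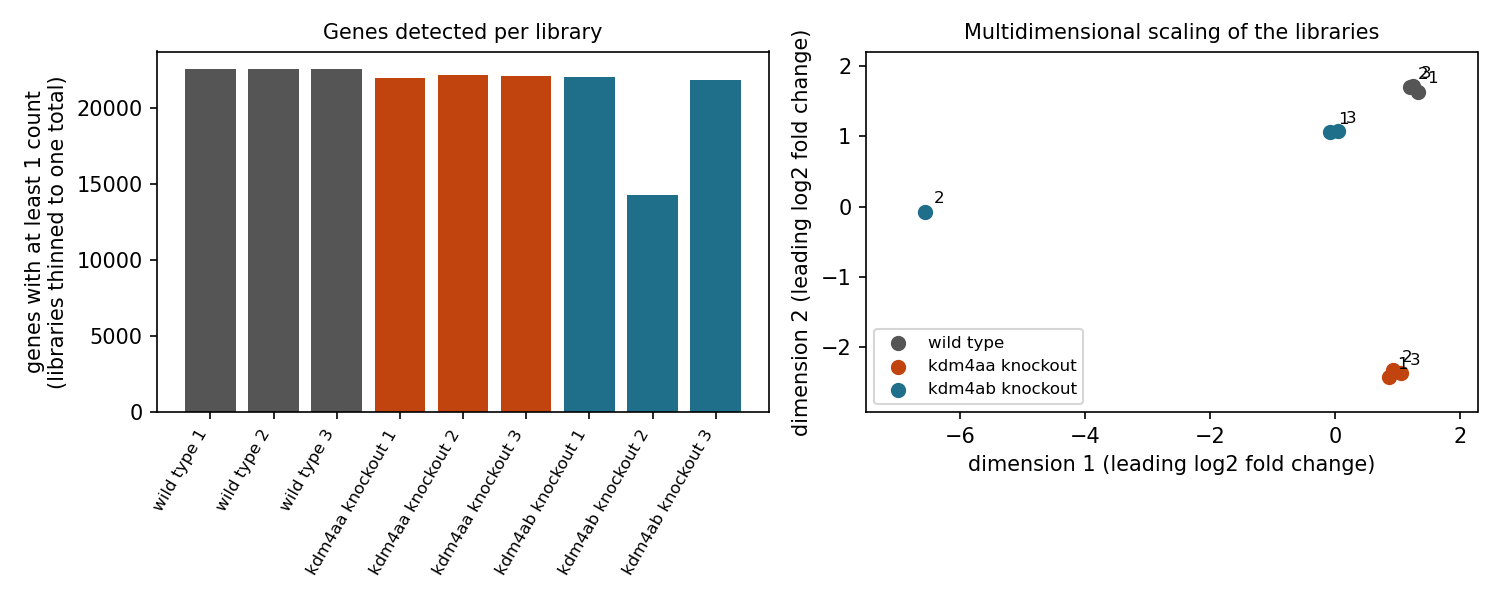
Left, bars give the number of genes with at least 1 count in each library after thinning to the lowest total. Right, each point is a library placed by multidimensional scaling of leading log2 fold changes and numbered by replicate; kdm4ab knockout replicate 2, with 14247 genes, lies apart from the other 8 libraries.

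The transcript of kdm4ab (ENSDARG00000019103) was nearly absent from the kdm4ab knockout. It stood at 2.379, 0 and 2.216 CPM in replicates 1, 2 and 3, against 139 ± 25.5 CPM in wild type and 158 ± 12.5 CPM in the kdm4aa knockout. The log2 fold change against wild type was −6.47 (SE 1.01, adjusted p 0.00438 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and −5.91 without replicate 2. The transcript of kdm4aa (ENSDARG00000018782) was not lowered detectably in its own knockout, at 16.6 ± 1.65 CPM against 19.1 ± 1.34 CPM in wild type, a log2 difference of −0.20 (SE 1.17, adjusted p 0.961). Its level therefore does not check the labels of the kdm4aa knockout libraries. In the kdm4ab knockout kdm4aa was at 13.95, 0 and 15.78 CPM, a log2 difference from wild type of −0.94 (SE 1.18, adjusted p 0.624). It was called lower there only without replicate 2 (log2 −0.35, adjusted p 0.0393), and over all alternatives the adjusted p ran from 0.0393 to 0.849.

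The study's gene, cyp26a1 (CYP26A1, ENSDARG00000033999), was at 62.9 ± 1.89 CPM in the kdm4aa knockout and 88.4 ± 12.3 CPM in wild type. All 3 knockout libraries lay below all 3 of wild type, and the log2 difference of −0.49 (SE 0.166) had an adjusted p of 0.121 in edgeR's quasi-likelihood test. Leaving out kdm4ab knockout replicate 2 gave −0.49 with an adjusted p of 0.000839, and over all alternatives the adjusted p ran from 0.000472 to 1. In the kdm4ab knockout cyp26a1 was at 117 ± 20.1 CPM, a log2 difference from wild type of 0.40 (adjusted p 0.137), with overlapping groups. The knockouts differed from each other: cyp26a1 was lower in the kdm4aa knockout (log2 −0.89, SE 0.167, adjusted p 0.00893), in 3 of 3 libraries. This call was not kept when tested against a fold of 1.5 with glmTreat (adjusted p 0.109), and over all alternatives the adjusted p ran from 2.48e-05 to 0.109. The study chose this gene on these samples, so its direction is not independent evidence.

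**Figure D2:**
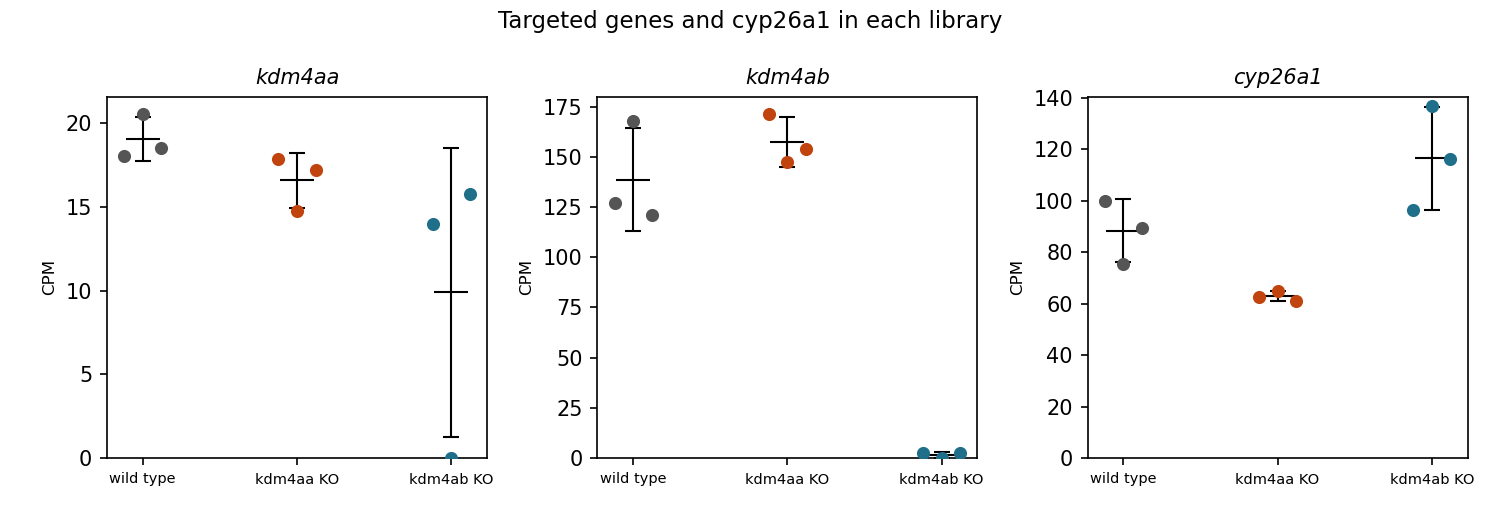
CPM of kdm4aa, kdm4ab and cyp26a1 in the 3 genotypes; each point is a library, and lines give the mean ± SD (n = 3). The kdm4ab transcript was at 1.53 ± 1.33 CPM in its knockout, while kdm4aa was at 16.6 ± 1.65 CPM in its own.

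In the kdm4aa knockout, 4 of 24 DNA damage response genes and 5 of 12 primordial germ cell genes rose against wild type, and 3 of 17 epidermal genes fell. Camera called these 3 lists at the preset correlation (adjusted p 0.00313, 0.00533 and 0.00313), and none of them with an estimated correlation (adjusted p 0.175 each). GADD45A (ENSDARG00000043581), a growth arrest gene induced by DNA damage, rose from 4.07 ± 0.770 to 17.2 ± 3.73 CPM, a log2 fold change of 2.08 (SE 0.244, adjusted p 0.00176). The apoptosis inducer bbc3 rose from 5.07 ± 1.24 to 22.3 ± 5.12 CPM (log2 2.14, adjusted p 0.00539). NANOS3 rose from 8.85 ± 1.88 to 32.2 ± 2.22 CPM (log2 1.86, adjusted p 0.00163). TP63, an epidermal factor, fell from 7.57 ± 0.564 to 2.41 ± 0.196 CPM (log2 −1.65, adjusted p 0.00654). Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

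Of 24 tested DNA damage response genes, 4 rose, and 6 when adjusted over the list alone. Among them was sesn2 (log2 1.49, adjusted p 0.0127). The list's median log2 fold change was 0.572 (camera, Up, adjusted p 0.00313, and adjusted p 0.175 with an estimated correlation). Of 37 genes of the apoptosis machinery, 2 rose and 2 fell, the same counts when adjusted over the list alone (camera adjusted p 0.848, and adjusted p 0.98 with an estimated correlation). The called members go both ways in function. bcl2a, which protects cells from death, fell from 16.7 to 6.18 CPM (log2 −1.43, adjusted p 0.00299), and xiap, an inhibitor of cell death, rose by 0.85 on the log2 scale (adjusted p 0.0151). The death promoter bada rose (log2 2.25, adjusted p 0.0248). Of 30 heat shock and unfolded protein genes, 7 rose, and 8 when adjusted over the list alone, with a median of 0.274 (camera, Up, adjusted p 0.00681, and adjusted p 0.175 with an estimated correlation). The cytosolic chaperone HSP90AB1 rose from 1123 ± 46.6 to 2163 ± 146 CPM (log2 0.95, adjusted p 0.00947). HSP90B1 and PDIA4 rose by 0.62 and 0.68 (adjusted p 0.0126 and 0.0218). In the fit of the 8 libraries without kdm4ab knockout replicate 2, 13 rose and 2 fell of the DNA damage response list, 13 and 5 of the apoptosis list, and 13 and 2 of the heat shock list. Of all genes tested in that fit 46.8% were called, and list counts from it should be read beside this share.

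Of 12 primordial germ cell genes, 5 rose, and 6 when adjusted over the list alone, with a median of 0.576 (camera, Up, adjusted p 0.00533, and adjusted p 0.175 with an estimated correlation). They include tdrd5 of the germ granule, from 29.7 to 79.8 CPM (log2 1.43, adjusted p 0.00402), and DND1, which protects germ cell messages, from 22.2 to 62.8 CPM (log2 1.5, adjusted p 0.0449). Of 26 maternal oocyte transcripts, 3 rose, also when adjusted over the list alone, with a median of 0.255 (camera, Up, adjusted p 0.0435, and adjusted p 0.98 with an estimated correlation). These were cth1, from 365 ± 47.8 to 800 ± 104 CPM (log2 1.13, adjusted p 0.00532), the claudin gene cldnd, from 155 ± 20.7 to 1015 ± 206 CPM (adjusted p 0.0334), and the germ cell gene DAZL (log2 1.18, adjusted p 0.0421). The maternal list was not called without wild-type replicate 1 (camera adjusted p 0.0771) or kdm4aa knockout replicate 1 (0.0698). Of 17 genes of the epidermis, ionocytes and periderm, 3 fell, and 5 when adjusted over the list alone, with a median of −0.771 (camera, Down, adjusted p 0.00313, and adjusted p 0.175 with an estimated correlation). Beside TP63 these were the envoplakin gene evpla, from 8.69 ± 0.952 to 1.86 ± 0.461 CPM (adjusted p 0.0155), and the keratin gene krt4, from 183 ± 24.5 to 87.3 ± 7.39 CPM (log2 −1.06, adjusted p 0.0321). With 8 libraries, 8 of 12 germ cell genes rose and 2 fell, 13 of 26 maternal transcripts rose and 1 fell, and of 21 epidermal genes then tested 1 rose and 12 fell.

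Of 28 interferon response genes, 1 rose and 4 fell, and 2 and 5 when adjusted over the list alone (camera, Down, adjusted p 0.26, and adjusted p 0.98 with an estimated correlation). The antiviral ubiquitin ligase gene trim25 rose from 7.37 ± 0.969 to 46.8 ± 1.66 CPM (log2 2.67, adjusted p 0.000142). TAP1, a peptide transporter of antigen presentation, fell from 10.5 to 0.434 CPM (log2 −4.59, adjusted p 0.000852), and gbp1, an interferon-induced GTPase, fell by 2.52 on the log2 scale (adjusted p 0.00468). Of 26 pluripotency and blastula genes, 2 fell, also when adjusted over the list alone (camera, Down, adjusted p 0.165, and adjusted p 0.98 with an estimated correlation). They were ved, a ventral homeobox gene, from 20.2 to 4.28 CPM (log2 −2.24, adjusted p 0.00723), and znfl2a (log2 −1.26, adjusted p 0.0289). Without wild-type replicate 2 this list was called (Down, camera adjusted p 0.0194, and adjusted p 0.25 with an estimated correlation). Of 51 cell cycle genes, 3 rose and 1 fell, the same counts when adjusted over the list alone (camera, Up, adjusted p 0.146, and adjusted p 0.688 with an estimated correlation). The mitotic kinase gene aurka, the replication gene CDC45 and the ribonucleotide reductase gene RRM1 rose by 0.68, 1.22 and 0.70, and the phosphatase gene cdc25b fell by 0.53. Of 14 notochord and cartilage genes, 1 rose and 1 fell, and 3 each when adjusted over the list alone (camera, Down, adjusted p 0.895, and adjusted p 0.98 with an estimated correlation). The lysyl oxidase gene loxl5b rose (log2 2.09, adjusted p 0.00149) and hapln1a, which links the cartilage matrix, fell (log2 −1.83, adjusted p 0.0207). The notochord median was −0.77 and its mean 0.0571. With 8 libraries, 4 rose and 10 fell of 31 interferon genes then tested, 1 and 11 of the blastula list, 22 and 6 of the cell cycle list, and 3 and 6 of 15 notochord and cartilage genes.

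No retinoic acid gene of 21 was called by edgeR's quasi-likelihood test, with 2 higher and 3 lower at an unadjusted p under 0.05, 2 called higher by DESeq2, and 8 of 23 higher and 7 lower without kdm4ab knockout replicate 2 (camera adjusted p 0.895, and adjusted p 0.98 with an estimated correlation). The receptor gene raraa was higher by 0.98 (adjusted p 0.092) and the synthesis enzyme gene ALDH1A2 by 2.53 (adjusted p 0.152). The list holds cyp26a1, which the study chose on these samples, so that member is not independent evidence of its direction. Of 74 cytosolic ribosomal protein genes none was called, with 1 higher at an unadjusted p under 0.05 and none called by DESeq2 among 47 it gave an adjusted p. Their median was 0.5 (camera, Up, adjusted p 0.0106, and adjusted p 0.98 with an estimated correlation), and 60 rose without kdm4ab knockout replicate 2 (camera, Up, adjusted p 1.38e-09, and adjusted p 0.87 with an estimated correlation). The mitochondrial genome list, with 2 of 13 genes higher at an unadjusted p under 0.05 and none called by edgeR or DESeq2, had a camera adjusted p of 0.098, and an adjusted p of 0.98 with an estimated correlation. It was called without kdm4aa knockout replicate 2 (0.0392) or 3 (0.0324), where the adjusted p with an estimated correlation was 0.944 and 0.99, and 8 of its 13 genes rose in the fit of 8 libraries.

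The largest fitted changes were in single genes. CTSB (ENSDARG00000055120), the lysosomal protease cathepsin B, fell from 1062 ± 30.7 to 0.177 ± 0.0547 CPM (log2 −12.54, SE 0.328, adjusted p 1.46e-06 by edgeR's quasi-likelihood test), with 1134 ± 275 CPM in the kdm4ab knockout. Also lower were FAM131C, at least 170-fold, the aminopeptidase gene ENPEP, at least 108-fold, the channel gene trpc2a, at least 98.9-fold, and dicp1.3-4, at least 72.4-fold, each with no count in the knockout, against a floor of 3 counts per library. With 1 or 2 counts in the knockout, the ratios of wild type to knockout were 2430 for ccdc15 (95% interval 436 to 96100), 784 for mslna (140 to 31000), 669 for the melanosome transport gene MLPH (185 to 5530), 626 for noxa1 (173 to 5180) and 569 for gmip (157 to 4710). Among genes that rose, RFLNB, which binds filamin, went from 1.25 ± 1.03 to 149 ± 16.9 CPM (log2 6.91, adjusted p 0.0047), and sspo, which encodes the SCO-spondin of the Reissner fibre, from 2.09 ± 0.152 to 130 ± 5.37 CPM (log2 5.96, adjusted p 0.000232). The plexin gene plxnb2a.2 rose from 1.1 to 67.5 CPM, gfra4a from 0.213 to 17.8 CPM, NEUROD6 (ENSDARG00000020794) from 0.110 to 11.5 CPM and the peroxidase gene epx from 0.14 to 10 CPM. LRRC30 had no count in wild type and was at least 126-fold higher, and B3GLCT (ENSDARG00000077740), with 2 counts in wild type, was 1030-fold higher (284 to 8480). fthl28 and epdl1 rose by 6.23 and 5.74 on the log2 scale. Leaving out wild-type replicate 1 moved the fitted values of RFLNB and fthl28 to 7.74 each, and leaving out wild-type replicate 3 moved that of epx from 6.11 to 6.96.

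In all, 1687 of 18998 genes were called, 823 higher and 864 lower, of which 1221 changed by at least 1 on the log2 scale. In the fit without kdm4ab knockout replicate 2, 9306 of 19882 genes were called, and all 1687 were among them with the same sign. That library is in neither group compared, so leaving it out mainly narrows the spread, and the kept calls are no check. The count was 612, 680 and 569 without wild-type replicate 1, 2 or 3, and 586, 653 and 625 without kdm4aa knockout replicate 1, 2 or 3. Of 61 named genes called in this comparison, each of these 6 fits lost between 26 and 30. Among them, xiap, bada, krt4, evpla, DND1, DAZL, cldnd, znfl2a, cdc25b, aurka, CDC45, RRM1, PDIA4, noxa1 and hapln1a were lost in all 6, and sesn2, HSP90AB1, HSP90B1, TP63, fthl28, gfra4a and gmip in some. Leaving out kdm4ab knockout replicate 1 ended the calls of DAZL and RRM1, and leaving out its replicate 3 that of RRM1. The knockout and wild-type values of the called list members named did not overlap, and for the genes with the largest fitted changes this was a condition of naming them.

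**Figure D3:**
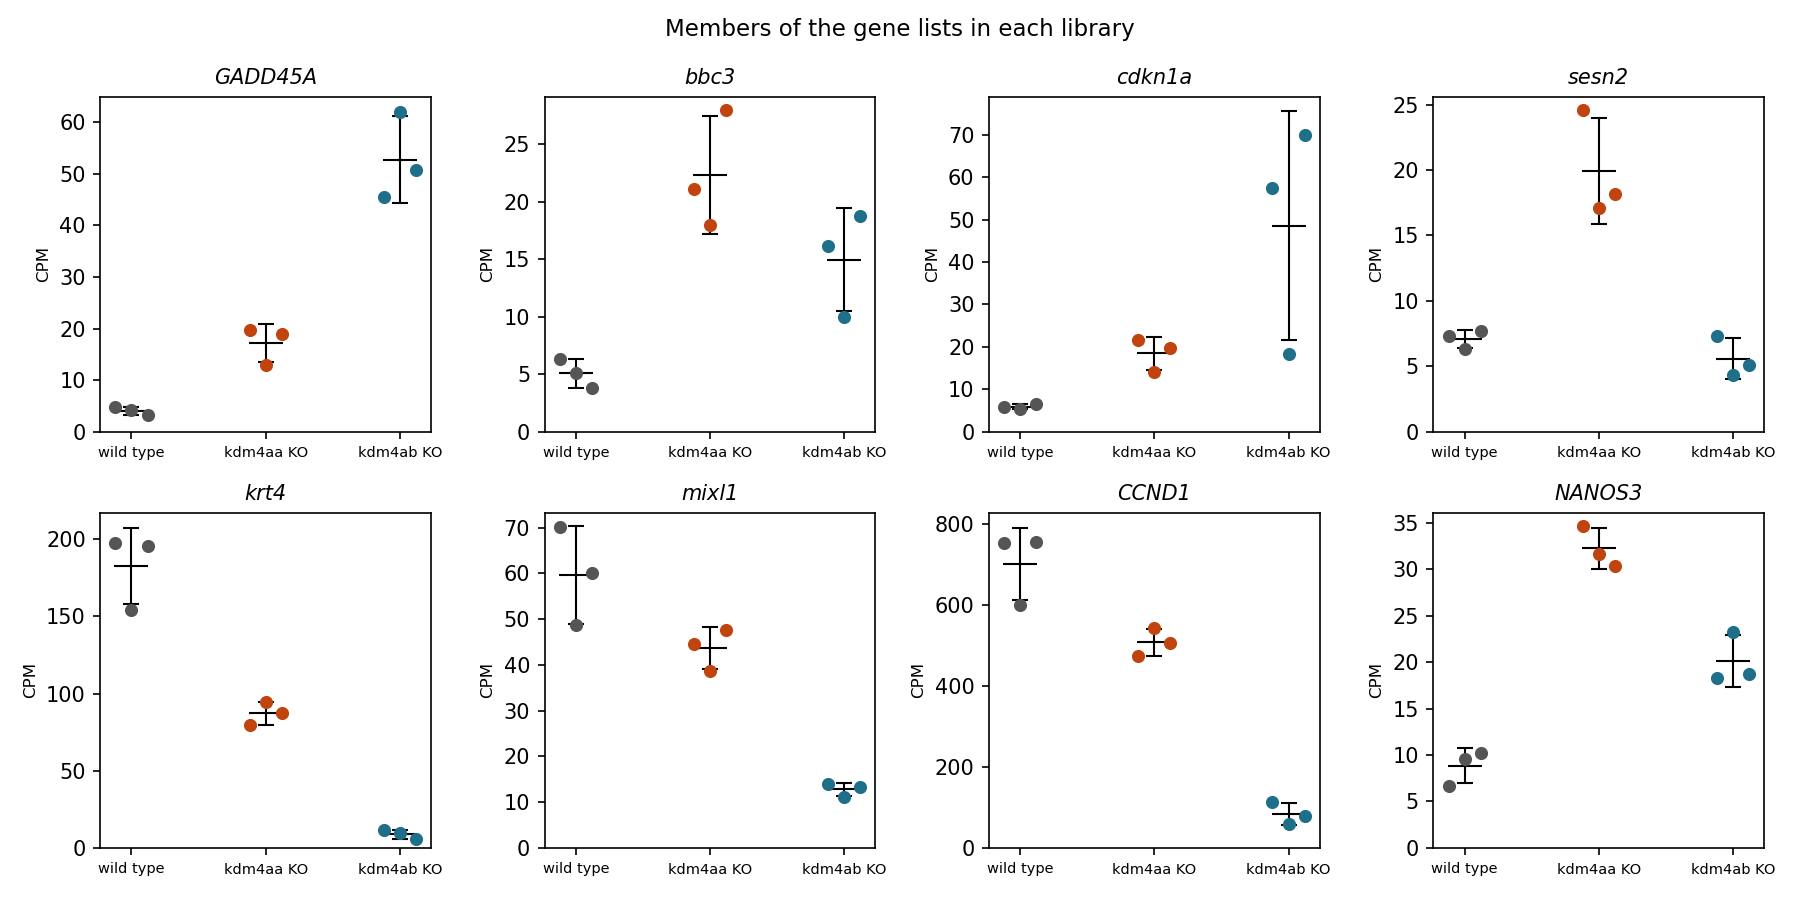
CPM of 8 members of the gene lists in the 3 genotypes; each point is a library, and lines give the mean ± SD (n = 3). Each axis starts at 0, and krt4 was at 183 ± 24.5 CPM in wild type, 87.3 ± 7.39 CPM in the kdm4aa knockout and 8.87 ± 2.91 CPM in the kdm4ab knockout.

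The remaining lists had 0 to 2 calls each in the kdm4aa knockout in the fit of all 9 libraries, and more without kdm4ab knockout replicate 2, as given after them. Of 18 somite and skeletal muscle genes 1 fell (median 0.119, camera Down, adjusted p 0.961), of 14 erythroid and globin genes 1 fell (adjusted p 0.878), of 11 endothelial genes 1 fell (0.652), of 10 photoreceptor genes 1 fell (median 0.431, camera Down, 0.961) and of 7 lens crystallin genes 2 fell (0.138). None was called by edgeR's quasi-likelihood test among 15 hox genes (2 higher at an unadjusted p under 0.05, DESeq2 2 higher, camera adjusted p 0.878), 14 myeloid genes (1 higher, DESeq2 1 lower, median −0.05, mean 0.282, camera Up, 0.895) or 30 neural genes (4 higher and 4 lower, DESeq2 2 higher and 3 lower, 0.878). None was called among 5 hatching gland genes (1 lower at an unadjusted p under 0.05, DESeq2 none, median 0.0188, camera Down, adjusted p 0.895), 14 genes of the yolk syncytial layer, liver and lipoproteins (1 higher, DESeq2 1 higher, 0.294) or 5 genes of pancreas and intestine (1 lower, DESeq2 1 lower, median 0.504, mean −0.828, camera Down, 0.848). In the KDM4 family of 4 genes, too few for camera, none was called by edgeR or DESeq2, none had an unadjusted p under 0.05, and KDM4B differed by 0.23 (adjusted p 0.538). In the fit of 8 libraries, 8 rose and 7 fell of 30 neural genes, 6 and 1 of 17 genes of the yolk syncytial layer, liver and lipoproteins, 2 and 3 of 20 muscle genes, 2 and 3 of 12 endothelial genes, 2 and 2 of 11 photoreceptor genes, 1 and 4 of 14 erythroid genes, 3 and 1 of 14 myeloid genes, 1 and 2 of 8 lens genes and 1 and 2 of 7 pancreas and intestine genes. There, 4 of 18 hox genes and 1 of the 4 KDM4 genes rose, and 1 of 5 hatching gland genes fell. With an estimated correlation, the adjusted p of these lists with 9 libraries ran from 0.437 for the lens to 0.985. No list of any comparison was called with an estimated correlation, where the smallest adjusted p was 0.175, 0.129 and 0.278 in the 3 comparisons.

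In the kdm4ab knockout, 9 of 17 epidermal genes fell and 2 rose against wild type, 12 of 26 pluripotency and blastula genes fell and 1 rose, and 8 of 24 DNA damage response genes rose and 1 fell. Camera called these 3 lists at the preset correlation (adjusted p 7.64e-08, 5.64e-05 and 0.0215), and none of them with an estimated correlation (adjusted p 0.129, 0.358 and 0.332). The simple-epithelium keratin gene krt18a.1 fell from 230.0 ± 33.0 to 23.0 ± 4.11 CPM (log2 −3.32, SE 0.195, adjusted p 0.000109), and krt4 fell from 183 ± 24.5 to 8.87 ± 2.91 CPM (log2 −4.36, adjusted p 0.000127). The mesendoderm factor mixl1 fell from 59.6 ± 10.7 to 12.8 ± 1.42 CPM (log2 −2.22, adjusted p 0.000347), and CCND1, the cyclin that drives entry into the cell cycle, fell from 703 ± 89.2 to 83.9 ± 27.5 CPM (log2 −3.07, adjusted p 0.000267). GADD45A (ENSDARG00000043581) rose from 4.07 ± 0.770 to 52.8 ± 8.44 CPM (log2 3.70, adjusted p 0.000175). Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

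Of 17 genes of the epidermis, ionocytes and periderm, 9 fell and 2 rose, and 12 and 2 when adjusted over the list alone. The median was −2.42 (camera, Down, adjusted p 7.64e-08, and adjusted p 0.129 with an estimated correlation). krt8 fell from 125 ± 17.6 to 21.0 ± 5.45 CPM (adjusted p 0.000372), and evpla had no count in the knockout, at least 86.2-fold lower (adjusted p 0.000284). Of 26 pluripotency and blastula genes, 12 fell and 1 rose, and 16 and 1 when adjusted over the list alone, with a median of −0.788 (camera, Down, adjusted p 5.64e-05, and adjusted p 0.358 with an estimated correlation). Beside mixl1 these were klf2a, from 71.1 to 20.4 CPM (log2 −1.80, adjusted p 0.000624), and sox19a, from 183 to 60.6 CPM (adjusted p 0.000761). The member that rose is isg15, which the interferon list also holds. Of 51 cell cycle genes, 6 fell and 1 rose, the same counts when adjusted over the list alone (camera, Down, adjusted p 0.394, and adjusted p 0.73 with an estimated correlation). TOP2A, which untangles DNA, fell from 93.0 to 32.5 CPM (log2 −1.52, adjusted p 0.000413), and the replication helicase gene MCM3 fell from 102 to 30.4 CPM (log2 −1.74, adjusted p 0.00173). Without kdm4ab knockout replicate 2, 15 fell and 2 rose of 21 epidermal genes then tested, 19 and 2 of the blastula list, and 15 and 5 of the cell cycle list. Of all genes tested in that fit 49.5% were called.

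Of 24 DNA damage response genes, 8 rose and 1 fell, and 10 and 2 when adjusted over the list alone, with a median of 0.711 (camera, Up, adjusted p 0.0215, and adjusted p 0.332 with an estimated correlation). The cyclin-dependent kinase inhibitor gene cdkn1a rose from 5.86 ± 0.585 to 48.5 ± 27.0 CPM (log2 3.05, adjusted p 0.00378), PHLDA3 from 7.28 to 24.7 CPM (log2 1.76, adjusted p 0.00864), and mdm2, a ubiquitin ligase gene, from 76.1 to 151 CPM (log2 0.99, adjusted p 0.0114). Of 37 genes of the apoptosis machinery, 1 rose and 2 fell (camera, Up, adjusted p 0.291, and adjusted p 0.73 with an estimated correlation), and none when adjusted over the list alone, where 8 were higher and 4 lower at an unadjusted p under 0.05 in edgeR. DESeq2, adjusted over all genes, called 4 of these 37 higher and 4 lower. The survivin gene BIRC5 rose (log2 1.61, adjusted p 0.0463, and 0.75 without kdm4ab knockout replicate 2), and AIFM1, a mitochondrial death factor, fell (log2 −0.55, adjusted p 0.02). Of 30 heat shock and unfolded protein genes, 6 rose and 3 fell, and 7 and 4 when adjusted over the list alone, with a median of 0.112 and a mean of −0.00239 (camera, Up, adjusted p 0.411, and adjusted p 0.73 with an estimated correlation). The disulfide isomerase gene PDIA6 rose from 141 ± 2.76 to 279 ± 15.7 CPM (log2 0.98, adjusted p 0.00101), and the small heat shock gene HSPB1 fell from 168 to 64.5 CPM (log2 −1.38, adjusted p 0.000968). With 8 libraries, 13 rose and 4 fell of the DNA damage response list, 10 and 7 of the apoptosis list, and 8 and 6 of the heat shock list, whose median was then −0.0623.

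Of 28 interferon response genes, 6 rose and 1 fell, the same counts when adjusted over the list alone (camera, Up, adjusted p 0.131, and adjusted p 0.73 with an estimated correlation). trim25 rose from 7.37 ± 0.969 to 44.9 ± 3.48 CPM (log2 2.61, adjusted p 0.00012), isg15 from 24.2 ± 6.95 to 130 ± 14.7 CPM (log2 2.42, adjusted p 0.00131) and irf3, a transcription factor of the antiviral response, by 4.02 (adjusted p 0.00446). Of 26 maternal oocyte transcripts, 6 rose, and 7 when adjusted over the list alone, with a median of 0.854 (camera, Up, adjusted p 0.000318, and adjusted p 0.73 with an estimated correlation). The egg coat gene zp3b rose from 61.1 ± 2.78 to 206 ± 113 CPM (log2 1.75, adjusted p 0.00935), and the oocyte growth factor genes GDF9 and bmp15 rose by 0.70 and 1.38 (adjusted p 0.0236 and 0.0312). Of 12 primordial germ cell genes, 3 rose, and 6 when adjusted over the list alone, with a median of 0.544 (camera, Up, adjusted p 0.0471, and adjusted p 0.332 with an estimated correlation). NANOS3 rose from 8.85 ± 1.88 to 20.1 ± 2.77 CPM (log2 1.18, adjusted p 0.00763). When kdm4ab knockout replicate 2 was left out, neither the maternal list (camera adjusted p 0.196) nor the germ cell list (0.148) was called. The maternal median moved to 0.195, with 10 higher and 2 lower, and the germ cell median to 0.271, with 7 higher and 2 lower, and of 31 interferon genes then tested 13 rose and 6 fell. The germ cell list was not called without kdm4aa knockout replicate 2 either (0.0507).

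Of 14 genes of the yolk syncytial layer, liver and lipoproteins, 3 fell, also when adjusted over the list alone, with a median of −1.08 (camera, Down, adjusted p 0.0534, and adjusted p 0.332 with an estimated correlation). The list was called without wild-type replicate 3 (0.0353) or kdm4ab knockout replicate 1 (0.0369), where the adjusted p with an estimated correlation was 0.394 and 0.353. HNF4A, a transcription factor of liver and gut, fell from 11.4 to 0.451 CPM (adjusted p 0.011), and MTTP and APOB, which assemble lipoproteins, fell with log2 fold changes of −4.76 and −4.60 (adjusted p 0.0213 and 0.0431). Leaving out kdm4ab knockout replicate 1 moved the log2 fold change of HNF4A from −4.60 to −5.46, of MTTP to −9.56 and of APOB to −4.00, and leaving out its replicate 3 moved APOB to −8.11. Of 14 notochord and cartilage genes, 1 rose and 3 fell, the same counts when adjusted over the list alone (camera, Down, adjusted p 0.432, and adjusted p 0.731 with an estimated correlation). tbxta, the brachyury gene that specifies mesoderm and notochord, fell from 22.9 ± 4.2 CPM (log2 −4.36, adjusted p 0.0198), and the notochord factor noto fell from 35.9 to 9.85 CPM (adjusted p 0.00807). Of 21 retinoic acid genes, 2 rose and 1 fell, the same counts when adjusted over the list alone (camera, Up, adjusted p 0.752, median −0.05, mean 0.46, and adjusted p 0.843 with an estimated correlation). The binding protein gene CRABP1 (ENSDARG00000035904) rose from 0.00849 to 4.12 ± 3.35 CPM (adjusted p 0.00235), raraa rose from 2.47 to 8.54 CPM (log2 1.79, adjusted p 0.00674), and CRABP2 (ENSDARG00000030449) fell from 16.6 to 0.993 CPM (log2 −4.04, adjusted p 0.0252). The mean of CRABP1 rests in part on kdm4ab knockout replicate 2, at 7.97 CPM against 1.82 and 2.58 CPM in replicates 1 and 3. Its fitted log2 fold change was 8.5, 7.61 without that library, and 10.33 without wild-type replicate 1. Of 74 cytosolic ribosomal protein genes none was called by edgeR's quasi-likelihood test, with 1 higher and 1 lower at an unadjusted p under 0.05 and 1 called lower by DESeq2. Their median was 0.92 (camera, Up, adjusted p 0.00569, and adjusted p 0.774 with an estimated correlation). Without kdm4ab knockout replicate 2 their median was −0.359, with 43 lower and 1 higher (camera, Down, adjusted p 0.00089, and adjusted p 0.741 with an estimated correlation). In that fit 6 of 17 genes of the yolk syncytial layer, liver and lipoproteins fell, 2 rose and 4 fell of 15 notochord and cartilage genes, and 5 each of 23 retinoic acid genes, whose median was then 0.299.

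The largest fitted changes included c7b, a complement component, from 85.6 ± 3.22 to 0.0594 ± 0.0521 CPM (log2 −10.29, SE 0.474, adjusted p 4.3e-05 by edgeR's quasi-likelihood test), and the interferon lambda receptor gene ifnlr1, from 43.6 ± 0.866 to 0.330 ± 0.314 CPM (log2 −6.95, adjusted p 0.00117). ccdc15 and GAD1 (ENSDARG00000093411), a glutamate decarboxylase gene, had no count in the knockout and were at least 221-fold and 62.2-fold lower against 3 counts per library. The chemokine receptor gene CXCR3 was 1340-fold lower (95% interval 369 to 11000) and trpc2a 355-fold (121 to 1730), with 2 and 3 counts in the knockout. NCK1 (ENSDARG00000074262), PAPPA (ENSDARG00000059858) and dicp1.3-4 fell, with log2 fold changes of −7.88, −8.68 and −6.98. TRPM6, a magnesium channel gene, rose from 0.884 ± 0.198 to 49.1 ± 29.7 CPM (log2 5.79, adjusted p 0.000709), and taco1 from 0.234 to 26.3 CPM (log2 6.80, adjusted p 0.000446). NEUROD6 (ENSDARG00000020794) rose from 0.110 to 21.4 CPM, CHST15 from 0.211 to 17.2 CPM, the dynein gene DNAI2 from 0.198 to 14.5 CPM, kcnn1b from 0.0564 to 12.1 CPM, MYOM1 (ENSDARG00000104836) from 0.206 to 11.9 CPM, GGACT (ENSDARG00000070581) from 0.0345 to 5.98 CPM and TMEM244 from 0.0810 to 5.64 CPM. map4k2, with 2 counts in wild type, was 350-fold higher (96.5 to 2900). Leaving out kdm4ab knockout replicate 2 moved the fitted fold of TMEM244 from 66.9 to 29.4, of kcnn1b from 201 to 121 and of NEUROD6 from 185 to 116. On the log2 scale, leaving out its replicate 1 gave −7.77 for ifnlr1, −10.34 for NCK1 and −8.04 for PAPPA, and leaving out its replicate 3 gave −12.49 for PAPPA, −7.93 for dicp1.3-4 and 5.17 for MYOM1, which was at 5.82. Of wild type, leaving out replicate 1 gave 7.45 for taco1 and 6.89 for DNAI2, which was at 6.18, and leaving out replicate 2 or 3 gave 10.87 or 6.77 for GGACT, which was at 7.36.

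In all, 3232 of 18998 genes were called, 1705 higher and 1527 lower, of which 2419 changed by at least 1 on the log2 scale. Without kdm4ab knockout replicate 2, 9848 of 19882 genes were called, 3230 of the 3232 among them with the same sign. As the spread narrows, this is no check. The count was 1228, 1634 and 1219 without wild-type replicate 1, 2 or 3. Of 76 named genes called in this comparison, these 3 fits lost 17, 13 and 21, among them AIFM1, BIRC5, ripk1l, GDF9, bmp15, cldnd, tbxta, MTTP, APOB and CRABP2 (ENSDARG00000030449) in all 3, MYOM1 (ENSDARG00000104836) without wild-type replicate 1 or 3, and PHLDA3, mdm2 and zp3b without replicate 3. BIRC5, GDF9, bmp15, MTTP, APOB and CRABP2 were also lost without each kdm4aa knockout replicate, ripk1l without replicate 1 of these, CRABP2 and APOB without kdm4ab knockout replicate 1, and ripk1l without its replicate 3. The fit with only the kdm4ab knockout and wild type lost 27 of the 76, among them NANOS3, HNF4A, noto, tbxta, MTTP, APOB, mdm2, zp3b, GDF9, bmp15, AIFM1, BIRC5, CRABP2 and MYOM1. The values of the called list members named did not overlap between the groups, which was again a condition for the genes with the largest fitted changes.

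**Figure D4:**
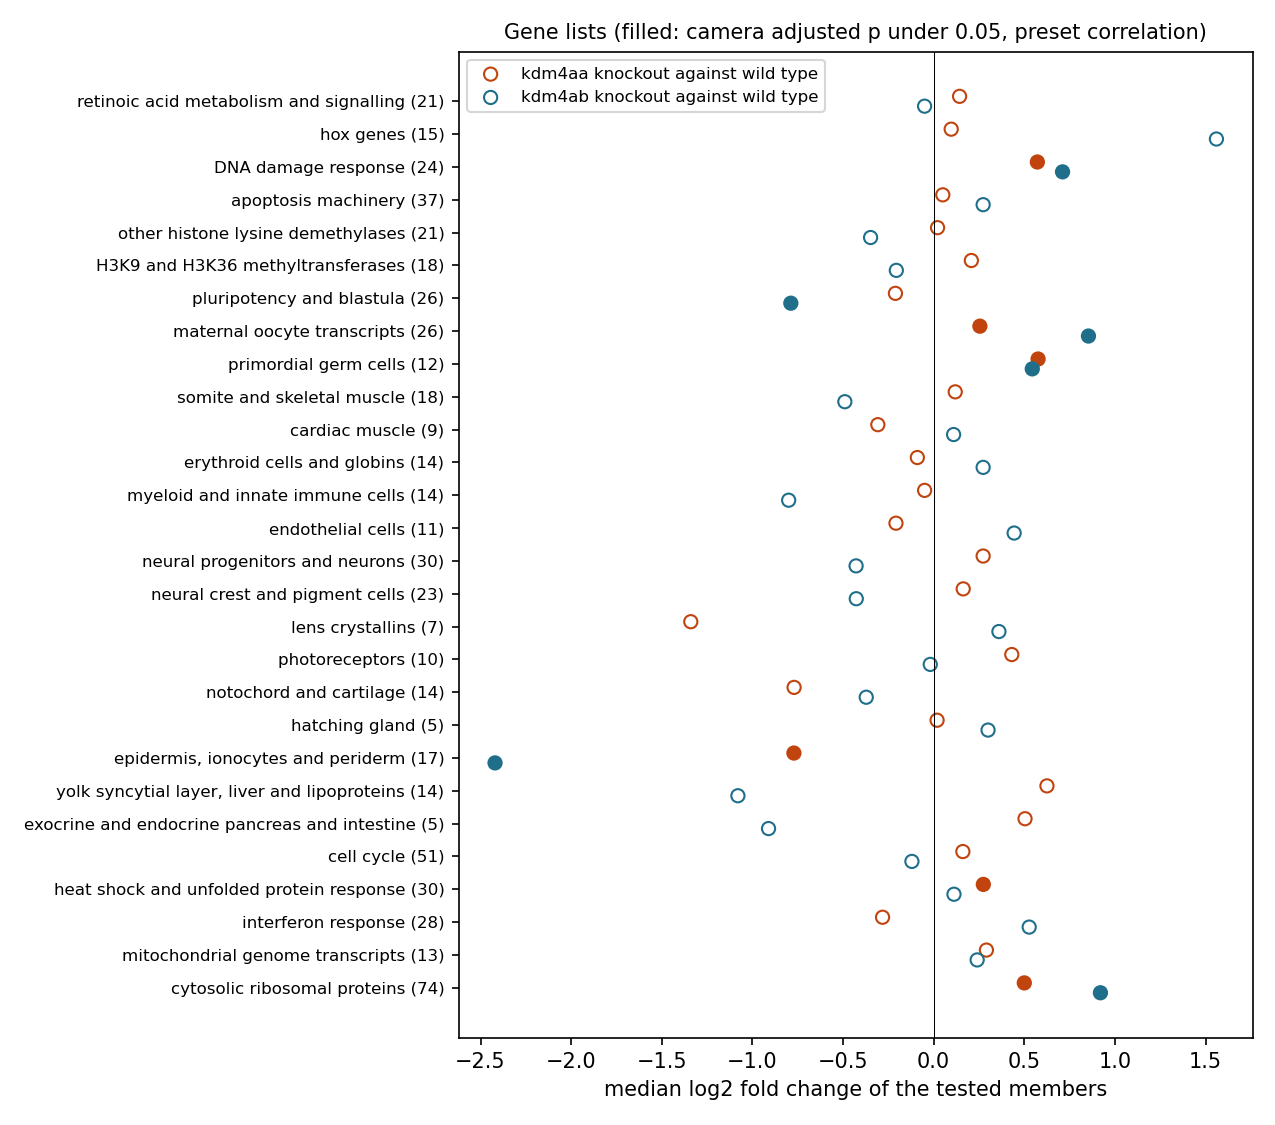
Median log2 fold change of the tested members of each gene list against wild type, with the number of members in parentheses, in the kdm4aa knockout (orange) and the kdm4ab knockout (blue). Filled circles were called by camera at the preset correlation; the epidermal list lies at −0.771 and −2.42.

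The direct comparison of both knockouts asked where they differ. Of 17 epidermal genes, 7 were higher and 1 lower in the kdm4aa knockout than in the kdm4ab knockout, of 26 blastula genes 9 and 1, and of 28 interferon response genes 1 and 7, while 10 of 51 cell cycle genes and 5 of 14 genes of the yolk syncytial layer, liver and lipoproteins were higher. Camera called these 5 lists at the preset correlation, and none with an estimated correlation (adjusted p 0.362, 0.628, 0.628, 0.628 and 0.278 in this order). krt18a.1 was at 181 ± 20.1 against 23.0 ± 4.11 CPM (log2 2.98, SE 0.192, adjusted p 0.000143), CCND1 at 508 ± 34.2 against 83.9 ± 27.5 CPM (log2 2.60, adjusted p 0.000407), and HNF4A at 14.7 ± 3.26 against 0.451 ± 0.435 CPM (log2 4.96, adjusted p 0.00794, and 5.82 without kdm4ab knockout replicate 1). TAP1 was at 0.434 ± 0.256 against 15.5 ± 1.62 CPM (log2 −5.15, adjusted p 0.000347) and isg15 at 31.5 ± 9.68 against 130 ± 14.7 CPM (log2 −2.04, adjusted p 0.00238). Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

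Of 17 epidermal genes, 7 were higher and 1 lower, and 9 and 2 when adjusted over the list alone (median 1.24, camera Up, adjusted p 0.00361, and adjusted p 0.362 with an estimated correlation). Of 26 blastula genes, 9 were higher and 1 lower, and 12 and 1 when adjusted over the list alone (median 0.463, camera Up, adjusted p 0.00863, and adjusted p 0.628 with an estimated correlation). They include mixl1 (log2 1.77), klf2a (log2 1.64) and apela, a signalling peptide of early development (log2 2.07, adjusted p 0.00119). Of 51 cell cycle genes, 10 were higher, also when adjusted over the list alone (median 0.281, camera Up, adjusted p 0.0253, and adjusted p 0.628 with an estimated correlation), among them CCNE2 (log2 1.96, adjusted p 0.00134) and TOP2A (log2 1.34, adjusted p 0.000634). Of 14 genes of the yolk syncytial layer, liver and lipoproteins, 5 were higher, and 7 when adjusted over the list alone (median 1.87, or 1.6 with genes of a group at 0 set to their bound, camera Up, adjusted p 0.00667, and adjusted p 0.278 with an estimated correlation). Of 28 interferon genes, 1 was higher and 7 lower, and 1 and 8 when adjusted over the list alone (median −0.895, or −0.656 with bounds, camera Down, adjusted p 0.00857, and adjusted p 0.628 with an estimated correlation). The blastula, cell cycle and interferon lists were not called without kdm4ab knockout replicate 1 (camera adjusted p 0.0619, 0.0727 and 0.0619), nor the cell cycle list without replicate 3 (0.0727). In the fit of 8 libraries, 12 of 21 epidermal genes were higher and 4 lower, with a median of 2.01, as were 14 and 3 of the blastula list, 30 and 4 of the cell cycle list, 9 and 1 of 17 genes of the yolk syncytial layer, liver and lipoproteins, and 3 and 16 of 31 interferon genes. Of all genes tested in that fit 52.8% were called.

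Of 24 DNA damage response genes, 4 were higher and 3 lower, and 4 each when adjusted over the list alone (camera, Down, adjusted p 0.833, and adjusted p 0.941 with an estimated correlation). GADD45A (ENSDARG00000043581) was lower (log2 −1.62, adjusted p 0.00315), while sesn2 was higher (log2 1.84, adjusted p 0.00326). Of 21 retinoic acid genes, 2 were higher and 3 lower, also when adjusted over the list alone (camera, Down, adjusted p 0.834, median 0.368, mean −0.208, and adjusted p 0.941 with an estimated correlation). Of 74 ribosomal protein genes 1 was higher (median −0.48, camera Down, adjusted p 0.574, and adjusted p 0.953 with an estimated correlation), and without kdm4ab knockout replicate 2, 73 were higher (median 0.804, camera Up, adjusted p 1.84e-18, and adjusted p 0.606 with an estimated correlation). Without kdm4ab knockout replicate 1 or 3 the ribosomal list was called lower (camera adjusted p 0.0173 and 0.00832), as were maternal transcripts (0.00399 and 0.00832). With an estimated correlation the adjusted p was 0.933 and 0.938 for the ribosomal list and 0.867 and 0.848 for the maternal list. In the fit of 8 libraries, 6 were higher and 10 lower of the DNA damage response list, and 4 and 7 of 23 retinoic acid genes, whose median was then −0.0524. Among single genes, CTSB (ENSDARG00000055120) was lower (log2 −12.64, adjusted p 1.4e-06), c7b was higher by 9.68 (adjusted p 6.12e-05), and OCA2, a pigment gene, and RAB27B had no count in the kdm4aa knockout and were at least 93.9-fold and 73.1-fold lower. The fitted log2 value of RAB27B was −11.01, and −10.41 without kdm4ab knockout replicate 2.

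In all, 3457 of 18998 genes were called, 1674 higher and 1783 lower in the kdm4aa knockout, of which 2488 differed by at least 1 on the log2 scale. Without kdm4ab knockout replicate 2, 10499 of 19882 genes were called, 3454 of the 3457 among them with the same sign, again no check. The count was 1512, 1625 and 1462 without kdm4aa knockout replicate 1, 2 or 3, and 2263 without wild-type replicate 3. Of 71 named genes called in this comparison, the fits without kdm4aa knockout replicates lost 15, 12 and 14, among them tnfrsf1a, ALDH1A2, mcl1b, zp3b, tbxta, COL9A2 and apoeb in all 3. Leaving out any 1 library other than kdm4ab knockout replicate 2 ended the call of tbxta and COL9A2, and leaving out kdm4ab knockout replicate 1 also those of ALDH1A2 and apoeb. The fit with only both knockouts lost 19 of the 71, among them HNF4A, tnfrsf1a, ALDH1A2, mcl1b, zp3b, tbxta, COL9A2 and apoeb. The called list members named did not overlap between the knockouts, and the genes with the largest fitted differences were chosen on this.

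The fold changes of both knockouts against wild type had the same sign for 63.6% of 18998 genes, with a Pearson correlation of 0.389 and a Spearman correlation of 0.36 across genes. All 3 values lay below those of 20 simulations of unchanged groups against the same 3 wild-type libraries, which gave 65.9% to 67.4%, 0.479 to 0.510 and 0.438 to 0.465. Without kdm4ab knockout replicate 2 the share was 60.8%, against 64.2% to 65.4% simulated. Of genes called in both, 442 were higher in both, 253 lower in both and 99 opposite. Among them were GADD45A (ENSDARG00000043581), trim25, NANOS3 and loxl5b, higher in both, and krt4, evpla and trpc2a, lower in both. KDM2B (ENSDARG00000036593), SETD3 and TBX20 went opposite ways. Independent lists of these sizes would share 73.9 higher, 69.4 lower and 144 opposite. The observed covariance was 0.89, against 0.226 to 0.247 simulated, and without kdm4ab knockout replicate 2 it was 0.93 against 0.0573 to 0.0631. As 3 controls cannot be split into parts of at least 2 libraries, some or all of the excess may come from the shared controls. The simulations drew wild type with the spread between replicates only, without an offset common to its libraries. The genes called in both with the same sign numbered 695, and 211, 263 and 196 without wild-type replicate 1, 2 or 3, 255, 288 and 275 without kdm4aa knockout replicate 1, 2 or 3, and 4101 without kdm4ab knockout replicate 2. Those 4101 were 2184 higher and 1917 lower in both, beside 1349 opposite, where independent lists would share 1174, 1131 and 2305.

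**Figure D5:**
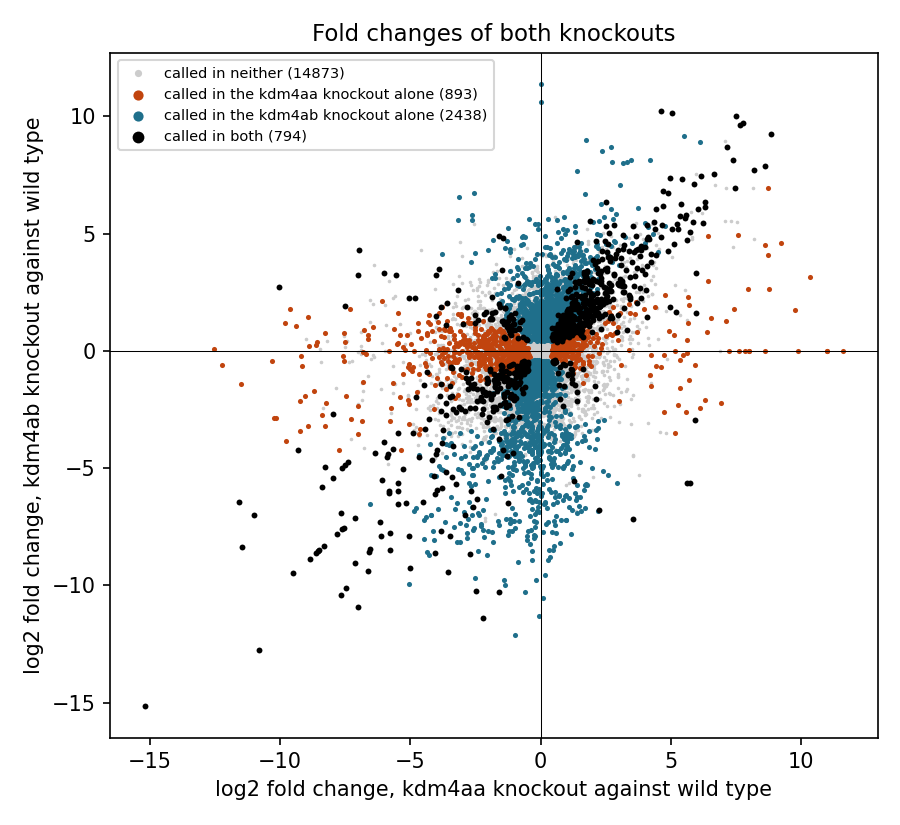
Log2 fold change against wild type of 18998 genes in the kdm4aa knockout (x axis) and the kdm4ab knockout (y axis); each point is a gene, coloured by where it was called. Of 794 genes called in both, 99 had opposite signs, and points far from 0 with few counts depend on the prior count.

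Genes near the targeted loci were called about as often as others. Within 10 Mb of kdm4aa, 13 of 142 tested genes (9.15%) were called in its knockout, against 8.91% of other placed genes (odds ratio 1.03, 95% interval 0.532 to 1.83, Fisher's exact p 0.882). On the whole chromosome that carries kdm4aa the odds ratio was 1.29 (p 0.0725). Within 10 Mb of kdm4ab, 18 of 131 genes (13.7%) were called, against 16.9% (odds ratio 0.783, 0.447 to 1.3, p 0.411), and on its chromosome the odds ratio was 1.03 (p 0.819). Adjusted over these 4 tests, the smallest p was 0.29. With the 8 libraries that exclude kdm4ab knockout replicate 2, 82 of 146 genes near kdm4aa were called (odds ratio 1.36, p 0.0671).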

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

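The tests on kdm4ab knockout replicate 2, the covariance without it and the chance order of neighbouring genes were chosen after the result was seen. A result stands here because edgeR's adjusted quasi-likelihood test between the knockouts showed that their effects against wild type differ. It called 3457 of 18998 genes (18.2%). Of 161 named genes, 90 differed, 54 higher and 36 lower in the kdm4aa knockout. Some named genes were chosen for a small p or large change here, so their share is no evidence. Of the 90, 43 had opposite signs against wild type, called there or not. CTSB, for example, had a log2 value of 0.094 in the kdm4ab knockout (edgeR adjusted p 0.778). All 90 kept call and sign without kdm4ab knockout replicate 2, no check as that fit called 52.8% of genes. Of 71 genes named for this comparison and called, each of the other 8 fits without 1 library lost 4 to 15, among them KDM7A, tbxta and COL9A2 in all 8. The fit with only both knockouts lost 19 of these, among them HNF4A, MTTP, apoa2, apoeb, atf4b, PDIA6, tnfrsf1a, ENDOG, mcl1b, ALDH1A2, RXRA (ENSDARG00000035127), KDM7A, setmar, zp3b, GATA6, tbxta, COL9A2 and hapln1a. Fitted values with a group at 0 to 3 counts depend on the prior count. The values are log2 differences of the kdm4aa knockout from the kdm4ab knockout.

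The epidermal list had a median of 1.24, or 2.01 without kdm4ab knockout replicate 2. krt4 differed by 3.3, krt18a.1 by 2.98 and krt8 by 2.08. evpla, at 1.86 CPM against no count in the kdm4ab knockout, had a fitted 9.19. The blastula list had a median of 0.463, with 2.07 for apela, 1.77 for mixl1, 1.64 for klf2a, 1.13 for sox19a and 0.43 for foxh1. The cell cycle list had a median of 0.281, with 2.6 for CCND1, 1.96 for CCNE2, 1.34 for TOP2A, 1.26 for ccnb3, 1.13 for MCM3 and 0.5 for aurka. The list of the yolk syncytial layer, liver and lipoproteins had a median of 1.87, or 1.6 with bounds. The values were 5.76 for MTTP, 4.96 for HNF4A, 0.98 for apoeb and a fitted 6.86 for apoa2, at 0.368 CPM against no count. The interferon list had a median of −0.895, or −0.656 with bounds, with −7.28 for mxc, −5.15 for TAP1, −3.7 for gbp1, −2.04 for isg15 and −1.83 for b2ml. Leaving out kdm4ab knockout replicate 1 gave 10.56 for MTTP and 5.82 for HNF4A, and leaving out kdm4aa knockout replicate 3 gave −9.99 for mxc.

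Heat shock and unfolded protein genes differed by 1.64 for HSPB1, 1.11 for atf4b, 0.62 for HSP90AB1 and −0.55 for PDIA6. In the DNA damage response list the values were 5.14 for tnfrsf1a, 1.84 for sesn2 and −1.62 for GADD45A. Genes of apoptosis differed by 1.23 for ENDOG, 0.88 for AIFM1, −1.07 for mcl1b and −1.19 for bcl2a. Retinoic acid genes differed by 4.9 for ALDH1A2, 3.59 for CRABP2, −0.89 for CYP26A1, −3.03 for RXRA (ENSDARG00000035127) and −6.14 for CRABP1. Histone demethylase and methyltransferase genes differed by 6.65 for kdm4ab, −1.2 for KDM7A, −1.25 for SETD3, −2.29 for setmar and −2.66 for KDM2B. Maternal transcripts differed by 0.9 for cth1 and −1.48 for zp3b. Cardiac genes differed by 5.38 for GATA5, 4.57 for GATA6 and −3.16 for TBX20, and neural crest and pigment genes by 3.25 for snai1b, 3.0 for DLX6, 1.98 for TFAP2C, 1.29 for TFAP2A and −11.37 for OCA2. Notochord and cartilage genes differed by 3.58 for tbxta, 3.56 for COL9A2, 2.03 for noto and −1.76 for hapln1a. Leaving out kdm4ab knockout replicate 2 gave −5.24 for CRABP1 and −1.41 for setmar, and leaving out its replicate 3 gave 7.77 for tnfrsf1a, 5.97 for GATA5, 5.68 for GATA6 and 4.2 for COL9A2.

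Outside the lists, genes higher in the kdm4aa knockout were LRRC30 by 11.58, epdl1 by 11.37, c7b by 9.68, RFLNB by 9.15, plxnb2a.2 by 8.9, epx by 8.54, B3GLCT by 8.01, RAC1 (ENSDARG00000099506) by 7.59, MCF2 (ENSDARG00000022895) by 6.96, PAPPA and ifnlr1 by 5.97 each, gfra4a by 5.58, sspo by 4.37 and GAD1 by 3.94. Lower in the kdm4aa knockout were CTSB at −12.64, noxa1 at −7.11, kcnn1b at −6.27, map4k2 at −4.68, CHST15 at −3.84, taco1 at −2.13 and DNAI2 at −1.49. FAM131C and RAB27B had no count there and were at least 113-fold and 73.1-fold lower, at fitted values of −11.64 and −11.01. With 1 or 2 counts there, the kdm4ab to kdm4aa knockout ratios were 851 for RIMS1 (235 to 7040) and 739 for gmip (204 to 6110). They were 675 for mslna (121 to 26700), 543 for klhdc8b (97 to 21500) and 441 for MLPH (122 to 3640). MCHR2 (ENSDARG00000007842) had 355 (98 to 2940). The fitted values of these genes were −9.43, −9.12, −8.98, −8.76, −8.49 and −8.4. Without kdm4ab knockout replicate 1, epx was at 11.57, B3GLCT at 12.30 and MCF2 at 7.63. Without replicate 2, RAB27B was at −10.41, MCHR2 at −7.63, noxa1 at −7.70 and kcnn1b at −5.57. Without replicate 3, RFLNB was at 10.75 and plxnb2a.2 at 10.36. Without kdm4aa knockout replicate 1, MLPH was at −11.27 and MCHR2 at −11.18. Without replicate 2, RIMS1 was at −12.21 and gmip at −11.91. Without replicate 3, mslna was at −10.90, klhdc8b at −10.68, RIMS1 at −8.83, gmip at −8.53, MLPH at −7.89 and MCHR2 at −7.81. In each comparison, only the real one of 10 splits of the 6 libraries called genes (1687, 3232 and 3457, against 0). 10 splits are too few for a share under 0.05.

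The first pattern is that kdm4ab knockout replicate 2 stands apart, with 14247 genes with a count. The other libraries thinned to its total kept at least 21793, which argues against lower sequencing depth alone. A wild-type or kdm4aa knockout library under this label is argued against by its 0 counts of kdm4ab, as 0.334% of genes at 50 to 500 CPM in the other kdm4ab knockout libraries were at 0 in it. Few distinct molecules behind its counts may be the source: it had 325 genes with 1 to 5 counts, where the lowest other library had 2512. Why there would be few was not tested, and a biological difference of these embryos stays open.

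The second pattern is that the covariance of both knockouts' fold changes lies above that of simulations with shared wild-type libraries. The share with the same sign, 63.6%, and the Pearson correlation, 0.389, lie below the simulated 65.9% to 67.4% and 0.479 to 0.510. The simulated groups were unchanged, and effects that differ between the knockouts lower both values. They therefore cannot decide whether genes share a common direction, and none across all genes is shown. The highest covariance of 20 simulations with shared wild-type libraries was 0.247, against 0.89 observed. This argues against the spread between wild-type replicates as the whole source. An offset common to all wild-type libraries was not simulated, so the shared controls could still be the whole source. Without kdm4ab knockout replicate 2 the covariance was 0.93, which argues against that library as the whole source. A slower development of both knockouts could also move genes together, which no stage series here tests, and the background of the lines was not tested by genotype.

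The third pattern is that called genes with large changes, at least 4 on the log2 scale, lie next to each other. Next to each other means consecutive among the tested genes, in the order of the deposited counts. The kdm4aa knockout had 14 adjacent pairs and the kdm4ab knockout 41, where the highest of 500 permutations of the order was 11 and 34 (one-sided permutation p 0.002, the smallest they can give). Outside the chromosome of the targeted gene 14 and 40 remained, above the highest permuted 10 and 33, which argues against a haplotype linked to that gene as the whole source. Without related or unnamed neighbours the pairs numbered 3 and 7, within the permuted range up to 9 and 24, so related neighbours that share reads or a name may account for the excess. This test also removes unnamed neighbours that were not shown to be related, and with 2.64 pairs expected by chance in the kdm4aa knockout it has little power.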

How the results depend on the processing

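Robust estimates and voom quality weights were chosen after the data were seen. For the kdm4aa knockout against wild type, the kdm4ab knockout against wild type and both knockouts against each other, in this order, DESeq2 called 3020, 5229 and 5359 genes. A fit with only the 2 groups compared called 9290, 1092 and 1259, where the first leaves out kdm4ab knockout replicate 2 by construction. Tested against a fold of 1.5 with glmTreat the counts were 717, 1591 and 1663, and with voom quality weights 9863, 10034 and 10096. Leaving out 1 library gave 569 to 9306, 1219 to 9848 and 1462 to 10499 calls, and 196 to 4101 genes called in both knockouts with the same sign. The highest of each came without kdm4ab knockout replicate 2, and the lowest without wild-type replicate 3, or kdm4aa knockout replicate 3 for the direct comparison. Where an alternative does not show it by its construction, the cause was not tested. Other scalings, voom, robust estimates and both filters kept the counts within 1.5 times, and no scaling moved the share of higher calls by over 10 percentage points. Voom shifted the median log2 value of all genes by −0.121 in the kdm4ab knockout against wild type and 0.118 between the knockouts, and quality weights by 0.167 and −0.168.

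For cyp26a1 in the kdm4aa knockout against wild type, the fit with only both groups gave −0.493 (adjusted p 0.000593) and voom quality weights −0.5051 (0.000472). Leaving out 1 library gave −0.5927 to −0.3929, with a call only without kdm4ab knockout replicate 2 (−0.4868, adjusted p 0.000839). For kdm4c, which passed in no comparison, the sign turned in the kdm4ab knockout against wild type with voom quality weights (0.105) and among the fits without 1 library (−0.6851 to 0.1283). It also turned between both knockouts (−0.1857, and −0.2191 to 0.5886). The odds ratio of called genes near kdm4aa was 0.863 in a window of 5 Mb. Lists called with an estimated correlation numbered 0, 0 and 0, against 4, 4 and 2 at an unadjusted p under 0.05, and fry called 5, 9 and 10.

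With the replicate number as a block, 765, 1807 and 2012 genes were called, and 294 in both knockouts with the same sign. Of 9 same-numbered pairs 3 had a correlation of deviations over 0.1, with a range of −0.206 to 0.368 over 11281 genes, and 3 libraries correlated best with one of their own number. The numbers therefore do not pair the samples. The list counts under the block were 6, 6 and 5. Counted once per gene and comparison, 214 results of named genes kept their side of the threshold under the block and 39 lost their call, 23, 8 and 8 by comparison, that of LRRC30 in the kdm4aa knockout among them. The test against a fold of 1.5 kept 203 and ended 50 calls, 23, 12 and 15 by comparison, that of cyp26a1 between both knockouts among them (adjusted p 0.109). With DESeq2 231 kept it and 21 more passed. Another scaling ended the calls of DAZL, DND1 and CDC45 in the kdm4aa knockout and of BIRC5 in the kdm4ab knockout. Voom ended those of gmip, KDM2B, kdm6bb and TBX20 in the kdm4aa knockout, of MYOM1 and BIRC5 in the kdm4ab knockout, and of gmip, KDM7A and setmar between both. Without a low-count filter SETD3, cdc25b and RRM1, then BIRC5, SETD3 and APOB, and then setmar, COL9A2 and apoa2 were lost. The many genes without a count in kdm4ab knockout replicate 2 limit what its group shows for genes of low level.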

Other observations

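Which gene lists are described here was chosen after their values were seen. Of 21 other histone lysine demethylase genes, 1 rose and 2 fell in the kdm4aa knockout, and 1 and 3 when adjusted over the list alone (median 0.0214, mean −0.336, camera Down, adjusted p 0.895, and adjusted p 0.98 with an estimated correlation). KDM1A, which removes methyl groups from lysine 4 of histone H3, rose from 65.7 ± 0.614 to 169 ± 5.1 CPM (log2 1.36, SE 0.213, adjusted p 0.00658 by edgeR's quasi-likelihood test), and was at 120 ± 35.3 CPM in the kdm4ab knockout (log2 0.87, adjusted p 0.0253). KDM2B (ENSDARG00000036593) fell from 28.5 ± 0.891 to 12.3 ± 1.08 CPM in the kdm4aa knockout (log2 −1.21, adjusted p 0.0334) and rose to 77.9 ± 29.9 CPM in the kdm4ab knockout (log2 1.45, adjusted p 0.0109), where 2 of the 21 rose, also when adjusted over the list alone (median −0.348, camera Down, adjusted p 0.776, and adjusted p 0.915 with an estimated correlation). kdm6bb fell from 13.4 ± 1.43 to 0.247 ± 0.203 CPM in the kdm4aa knockout (log2 −5.74, SE 1.43, adjusted p 0.0425). In the kdm4ab knockout kdm6bb was at 3.165, 0 and 4.212 CPM (log2 −2.44, adjusted p 0.199, and −1.86 with an adjusted p of 2.07e-05 without replicate 2). Its call in the kdm4aa knockout was lost with voom, under the replicate block, against a fold of 1.5 and without any 1 library other than kdm4ab knockout replicate 2. Without kdm4aa knockout replicate 1 the log2 value was −6.53. Of 18 methyltransferase genes for lysines 9 and 36, 1 fell in the kdm4aa knockout, also when adjusted over the list alone (camera adjusted p 0.878, and adjusted p 0.98 with an estimated correlation), and 3 rose in the kdm4ab knockout, or 3 rose and 1 fell when adjusted over the list alone (median −0.206, mean 0.135, camera Up, adjusted p 0.776, and adjusted p 0.904 with an estimated correlation). The member that fell is SETD3, from 52.4 ± 2.29 to 32.9 ± 2.27 CPM (log2 −0.67, adjusted p 0.0249). SETD3 rose to 78.2 ± 10.3 CPM in the kdm4ab knockout (log2 0.58, adjusted p 0.0275) and is known to methylate actin. All libraries of each knockout lay on 1 side of wild type for these genes. The calls of KDM2B and SETD3 in the kdm4aa knockout were lost in each fit without 1 wild-type or kdm4aa knockout library, which called 569 to 680 genes in all. In the kdm4ab knockout, those of KDM1A and SETD3 were lost without any 1 library other than kdm4ab knockout replicate 2, and that of KDM2B without wild-type replicate 1 or 3. All 3 were also lost there in the fit with only the kdm4ab knockout and wild type. In the fit without kdm4ab knockout replicate 2, 4 demethylase genes rose and 6 fell in the kdm4aa knockout, and 6 and 5 in the kdm4ab knockout (median −0.111). Of the methyltransferase genes 7 rose and 5 fell, and 5 and 4 in the kdm4ab knockout (median 0.155).

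Of 9 cardiac genes, 1 rose and 1 fell in the kdm4aa knockout (median −0.308, mean 0.226, camera Up, adjusted p 0.961, and adjusted p 0.985 with an estimated correlation), and 2 each in the kdm4ab knockout (median 0.11, mean −0.47, camera Down, adjusted p 0.776, and adjusted p 0.882 with an estimated correlation). Adjusted over the list alone, 1 each and then 3 and 2 were called. GATA5, a transcription factor of heart and endoderm, fell from 6.33 ± 2.62 to 0.194 ± 0.175 CPM in the kdm4ab knockout (log2 −4.95, adjusted p 0.00641 by edgeR's quasi-likelihood test), and GATA6 fell with it (log2 −4.88, adjusted p 0.00756). Without kdm4ab knockout replicate 3 the values were −5.54 and −5.99. The heart factor TBX20 rose there from 5.23 ± 0.296 to 18.4 ± 5.45 CPM (log2 1.81, adjusted p 0.00382) and fell in the kdm4aa knockout (log2 −1.35, adjusted p 0.0202). Of 23 neural crest and pigment genes, 1 rose and 5 fell in the kdm4ab knockout, and 2 and 6 when adjusted over the list alone (median −0.427, camera Down, adjusted p 0.0875, and adjusted p 0.73 with an estimated correlation). The list was called there without wild-type replicate 2 (0.0417, and adjusted p 0.753 with an estimated correlation). In the kdm4aa knockout 1 rose and 2 fell, also when adjusted over the list alone (median 0.163, mean −0.45, camera Down, adjusted p 0.895, and adjusted p 0.98 with an estimated correlation). snai1b, a factor of cell migration, fell from 26.6 ± 3.54 to 3.5 ± 2.04 CPM in the kdm4ab knockout (log2 −2.93, adjusted p 0.00218), and the crest factor TFAP2C from 20.9 ± 1.83 to 5.8 ± 1.36 CPM (log2 −1.85, adjusted p 0.00172). The groups of these genes did not overlap, and the TBX20 call in the kdm4aa knockout was lost in the same 6 fits as those of KDM2B and SETD3. The fit with only the kdm4ab knockout and wild type did not call GATA5 or GATA6. In the fit of 8 libraries, 2 cardiac genes rose and 3 fell in the kdm4aa knockout, and 3 each in the kdm4ab knockout (median −1.21), and 3 rose and 6 fell of the neural crest and pigment list, and 5 and 9 in the kdm4ab knockout (median −0.0736).

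Of the genes tested, 13 had no count in any of the 6 knockout libraries, and looking for such genes was decided after the data were seen. All but 1 were at 2.29 CPM or less in wild type. The exception, si:ch1073-190k2.1 (ENSDARG00000097973), also chosen after its values were seen, was at 117 ± 7.58 CPM in the 3 wild-type libraries. Against a floor of 3 counts per library it was at least 1300-fold lower in the kdm4aa knockout and at least 1160-fold lower in the kdm4ab knockout. As the gene was picked for its absence there, no p is given.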
